A study of Mus musculus with 2 samples.

How the data were processed

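Wild-type peripheral lung cells at postnatal day 3 were measured by single-cell RNA-seq (10x Chromium 3′ v3), and PDGFRA+ cells sorted from Pdgfra-H2BGFP peripheral lung at the same age by bulk RNA-seq, with 1 sample in each group. Per the submitters' processing notes, the single-cell data went through Cell Ranger 5.0 and Seurat 3.2.2, and the bulk data through Trim Galore, HISAT2, featureCounts and DESeq2 with mm10. The notes give no versions for the bulk tools, and the genome build of the single-cell table is not given in the sources used here. Whether animals were pooled is not stated.

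The deposited single-cell values were taken as a score: whole-number UMI values corrected for depth, not raw counts. That is inferred from the values themselves, and the step that made them is not known. Cell totals spanned only 1.79-fold, and in the 1000 cells with fewest genes 27.7% of the values above 0 were 1 and 32.5% were 2, against 74.3% and 12.4% in the 1000 with most genes. The plan fixed before the data were examined had assumed raw counts. Poisson intervals and conditional binomial intervals were therefore not given for single-cell levels, and thinning to a lower depth was not run. The deposited bulk table gives an expected count for each gene (15.9% of its values are not whole), a TPM and an FPKM value by the authors. It listed genes with reads only, 0 mitochondrial genes among them. The expected counts were used as CPM (scaled to a column total of 1000000), the deposited TPM as the alternative per kilobase, and the FPKM values were not used. Bulk depth was 171910584 reads, and bulk levels carry exact Poisson 95% intervals, which cover counting error only.

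Cells under 500 detected genes (0 cells) or over 10% mitochondrial UMIs (646 cells) were left out. Doublets were predicted with a re-implementation of the Scrublet score, with an expected share of 5% and the threshold at the minimum of the simulated scores. It removed 356 of 10660 cells (3.34%), which left 10304. Values were scaled to 10000 per cell and logged, and 2000 variable genes were chosen without mitochondrial and ribosomal protein genes or members of the fixed lists. From 30 principal components and 15 neighbours, Leiden clustering at resolution 1 gave 35 clusters. Each cluster took the name whose markers had the highest mean centred log2 level (at least 1). A cluster was left unnamed if another lineage scored 0.5 or more of the best score or, for mesenchymal and epithelial types, if its 10 most enriched genes held more markers of another type than of its own. Endothelial, myeloid and lymphoid types were pooled, and platelet markers were ignored for interstitial macrophages because these express Pf4. The marker lists were fixed before the data were examined, but these details of the naming rule were set afterwards.

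A class level is its summed corrected UMIs scaled to a total of 1000000 (CPM), and log2 ratios add 1 CPM to both sides. For each of 16 fixed lists, the median log2 ratio over members with at least 20 UMIs was set beside 10000 random lists of the same size matched on mean level within windows of 100 genes. The range given is the middle 95% of these random medians. It compares a list with other genes in the same cells and is not a test between samples. Medians with members at 0 set to a floor of 3 corrected UMIs per class were added after the data were examined. Shares of cells carry exact Clopper-Pearson 95% intervals, and a share of 0 in myofibroblast-like cells is given the limit that 3 cells allow. Counts of members at a log2 ratio of 1 or more, or -1 or less, are counts by size. Of the bulk symbols, 14974 matched the single-cell table directly and 15058 after alias matching. The bulk over library ratio adds 1 CPM to both sides.

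Genes were named by a rule fixed before the data were examined. It takes in each list up to 4 members with the largest absolute log2 ratio of myofibroblast-like over all other cells among those with at least 100 UMIs. It adds every ligand, acetylcholine receptor and adrenergic receptor gene with at least 20 UMIs, and Pdgfra. Of these, 2 are counted in their lists and not named. For bulk over library it takes the 10 highest and 10 lowest ratios among genes at 50 or more CPM in either table and 1 or more in both. Positions and exon overlaps are from GENCODE M21 on mm10.

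The steps were tested on simulated data. Planted log2 ratios of 1, 2, -1 and -2 were recovered as 0.95, 1.93, -0.94 and -1.82. Lists with no planted change lay outside the random range in 3.44% of draws, and lists raised 2-fold lay above it in 94.7%. In these draws the counts of both classes were Poisson, from a shared profile apart from the planted change. They stood for myofibroblast-like over other fibroblast-like cells only. Co-expression of list members and spread between cells were not simulated, so these rates cover counting error only. All simulated doublets (100%) and 0% of single cells were called. These cells were Poisson draws from the mean profiles of separate classes, and each doublet summed cells of different classes without depth correction. The rates therefore do not show how well doublets, above all of similar cells, were found in the real table. The simulated bulk ranked highest with its own class in 13 of 13 classes. Each simulated bulk was drawn from the profile of that class with no difference of assay, so this outcome was close to fixed in advance. It does not show whether the real bulk library can separate similar classes. The alternatives covered the cell filter, resolution, principal components, list genes among the variable genes, doublets, gene minimum, mean over cells, low bulk genes, TPM, pseudocount and the cells summed. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9.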

Results

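Peripheral lung of mice at postnatal day 3 was profiled in 2 samples, 1 in each of 2 groups. The first was a single-cell library (10x Chromium 3′ v3) of sorted cells from wild-type lung. The second was a bulk RNA-seq library of PDGFRA+ cells sorted from Pdgfra-H2BGFP mice, in which a nuclear green fluorescent protein is made from the Pdgfra locus. The single-cell table held 17758 genes in 11306 cells, with a median of 5537 depth-corrected UMIs per cell (a 1.79-fold span), 62575796 in all, and 709 to 3760 detected genes per cell (median 2012). The bulk table held 171910584 reads over 16906 genes. There were no replicates in either group, so no difference between groups was tested, and all intervals cover counting error only. Levels are given as CPM: bulk reads, or the summed depth-corrected UMIs of a class, scaled to a total of 1000000. Single-cell CPM carry no interval. Cell classes were named from marker genes and are called "-like" for that reason.

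The first question was which cell types the library held. Immune cells made up most of it: myeloid-like cells were 41.4% of the 10304 kept cells (exact Clopper-Pearson 95% interval 40.4% to 42.3%) and lymphoid-like cells 21.8% (21.0% to 22.6%). Endothelial-like cells were 9.95% (9.38% to 10.5%). Among mesenchymal cells, lipofibroblast or matrix fibroblast-like cells were 7.12% (6.63% to 7.64%) and myofibroblast-like cells 6.36% (5.89% to 6.85%). The myofibroblast-like class held 655 cells in 2 clusters, of 528 and 127 cells. Adventitial fibroblast-like cells were 2.73% (2.42% to 3.06%), smooth muscle-like cells 2.39% (2.10% to 2.70%) and pericyte-like cells 1.44% (1.22% to 1.69%). In the epithelium, alveolar type 2-like cells were 3.77% (3.41% to 4.15%), alveolar type 1-like cells 0.349% (0.245% to 0.483%) and ciliated-like cells 0.233% (0.149% to 0.346%). Mesothelial-like cells were 0.437% (0.319% to 0.584%), and 1 cluster of 217 cells, 2.11% (1.84% to 2.40%), stayed unnamed, with its highest marker score for secretory airway cells. That score was 2.57, beside 1.35 for megakaryocyte or platelet markers, which was enough to leave the cluster unnamed. Its median of detected genes was 1095. Leaving out cells under 1000 detected genes or over 5% mitochondrial UMIs moved the unnamed share to 4.74% and the pericyte-like share to 0.925%, and keeping predicted doublets moved the unnamed share to 6.22%. With every deposited cell the ciliated-like share was 0.365%. These are shares of a sorted suspension.

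**Figure D1:**
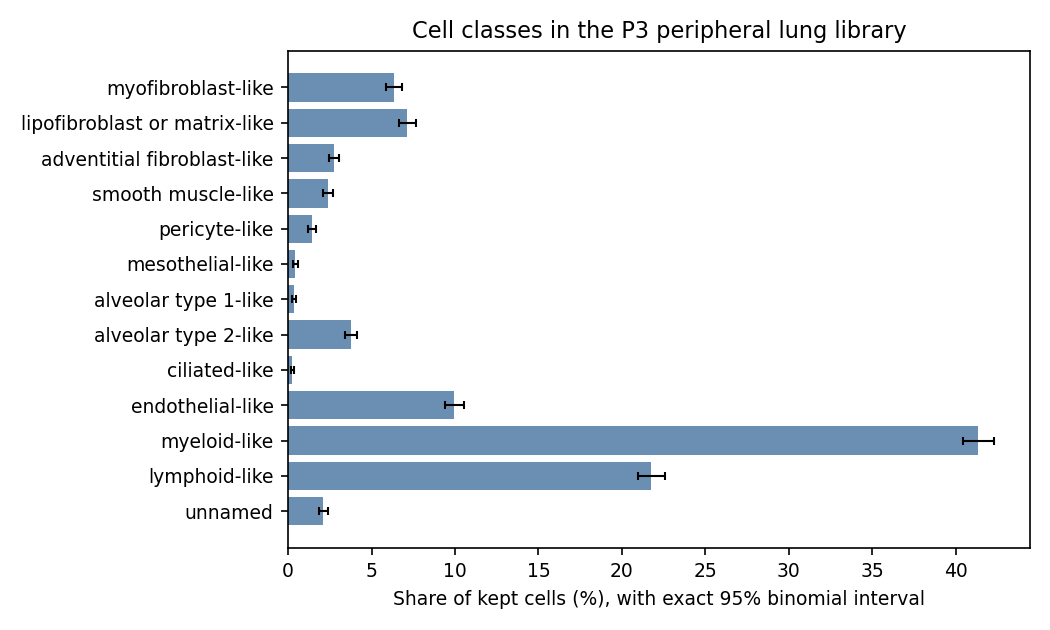
Bars give the share of the 10304 kept cells in each cell class, in percent, and whiskers the exact 95% binomial interval. Myeloid-like cells were 41.4% and myofibroblast-like cells 6.36%.

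The series title names autonomic nerves and myofibroblasts, so the myofibroblast-like cells were set against all other cells of the library. Myofibroblast-like cells had high levels of Nrtn, which encodes the GDNF-family ligand neurturin: 97.1 CPM against 3.83 in all other cells. They were also high in Wnt5a and Wnt11, ligands of non-canonical Wnt signalling, at 356 against 10.7 and 153 against 3.88 CPM. Genes for elastic fibres, collagens and the actomyosin machinery were higher as groups. Adrenergic receptor genes were lower as a group, although inside the random range with a stricter cell filter.

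Of the 6 measured neurotrophin and GDNF-family ligands, 4 were at a log2 ratio of 1 or more and none at -1 or less. The list median was 2.01, and the middle 95% of 10000 random lists matched on level lay at -0.94 to 1.01. Nrtn (ENSMUSG00000039481.5, mm10 chromosome 17, 56751325 to 56757530) had a log2 ratio of 4.35 and was detected in 39.8% (36.1% to 43.7%) of myofibroblast-like cells, against 0.281% (0.146% to 0.491%) of myeloid-like cells as background. Median detected genes were 2807 in myofibroblast-like and 1961 in myeloid-like cells. The ratios of Bdnf (ENSMUSG00000048482.14, mm10 chromosome 2, 109674700 to 109727007), Gdnf and Ntf3 were 2.87, 2.62 and 1.41. Of the 6 ligands only 3 (Nrtn, Bdnf and Ntf3) had at least 100 UMIs, so the ratio of Gdnf rests on fewer. Bdnf and Ntf3 had their highest levels in smooth muscle-like cells. Ntf5 was at -0.87. The 9 receptors of these ligands had a median of -0.14 (random -0.54 to 0.82), which was 0.15 with members at 0 set to a floor of 3 corrected UMIs. Gfra2, the preferred co-receptor of neurturin, stood at 2.16, Ntrk3 at 0.90, Sort1 at -0.82 and Ret, the signalling receptor, at -1.98. Among 18 axon guidance ligands 9 were at 1 or more and 6 at -1 or less, with a median of 0.70 (random -0.37 to 0.76). Ntn1 (3.01) and Sema3c (2.61) were at the upper end, and Sema3g (-3.01) and Slit3 (-2.52) at the lower end.

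Adrenergic receptors had a median log2 ratio of -1.14 (random -0.77 to 0.99), with 3 of 6 at -1 or less. Adrb1 stood at -2.69, Adra1b at -2.64 and Adrb3 at -0.94, and Adra2a at 1.49 was the member above 1. Adra1a was listed at 0 in the 655 myofibroblast-like cells, which allows a share of cells with a corrected UMI of up to 0.458%. The values are taken as depth-corrected, so this does not limit the share of cells with a raw UMI. Adra2a had 3.77 CPM and was detected in 1.83% (0.950% to 3.18%) of myofibroblast-like cells, against 0.633% (0.418% to 0.920%) of myeloid-like cells. Neuropeptide receptors had a median of -1.59 (random -1.34 to 0.96), or -1.22 with genes at 0 set to the floor (random -1.21 to 0.96), and were inside the random range with the stricter cell filter and with predicted doublets kept. Calcrl, a receptor subunit for calcitonin gene-related peptide, was at -3.61 and Vipr1 at -1.64, and Npy2r and Sstr2 were listed at 0 in myofibroblast-like cells. The 5 measured acetylcholine receptors had a median of -0.99, inside the random range of -1.19 to 1.10, or -0.46 with members at 0 set to the floor. Chrm2 was at 1.33, Chrm3 at -1.36 and Chrnb1 at -0.99, and Chrnb2 and Chrne were listed at 0 in myofibroblast-like cells. Genes of transmitter synthesis, uptake and breakdown had a median of 0.24 (random -0.53 to 0.76). Among them Bche, encoding butyrylcholinesterase, stood at 4.09, Ddc at 2.15, Maoa at 0.89 and Slc18a2 at -0.66.

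Of 19 elastic fibre genes, 14 were at a log2 ratio of 1 or more and 4 at -1 or less (median 1.82, random -0.49 to 0.48). Ltbp2 (4.79), Loxl2 (4.48) and Loxl3 (3.18) were higher, and Emilin2 (-3.85) had its highest level in myeloid-like cells. Collagens had a median of 1.52 (random -0.69 to 0.50), with Col12a1 at 4.44, Col5a1 at 2.93, Col5a2 at 2.17 and Col13a1 at -2.05. Actomyosin and adhesion genes had a median of 0.85 (random -0.69 to 0.25), led by Cald1 (3.22), Tpm2 (3.06), Tpm1 (2.97) and Myl9 (2.81). The planar cell polarity and non-canonical Wnt list had a median of 0.70 (random -0.12 to 0.64). Wnt11 (mm10 chromosome 7, 98835112 to 98855195) stood at 4.98, Wnt5a (mm10 chromosome 14, 28504750 to 28527448) at 4.93, the Wnt5a receptor gene Ror1 at 3.42 and Daam2 at 3.39. Growth factor and hedgehog signals had a median of 0.67 (random -0.38 to 0.56), with Igf1 at 4.57, Tgfb3 at 3.05 and Gli1 at 2.45, while Rspo1 was listed at 0 in myofibroblast-like cells. The PDGF list was at 0.14 (random -1.21 to 0.94): Pdgfra (ENSMUSG00000029231.15, mm10 chromosome 5, 75152292 to 75198215) stood at 4.81, Pdgfrb at 1.23, Pdgfc at 0.34 and Pdgfb at -3.43. Calcium handling (-0.16, random -0.27 to 0.57) and dissociation stress genes (-0.41, random -0.996 to 0.33) were inside their random ranges. Cacna1g was at 3.13, Itpr3 at -2.56, Orai2 at -2.28 and Orai1 at -1.89. Among stress genes Egr1 was at 1.39, Dusp1 at -1.38, Hspa1b at -1.02 and Hspa1a at -0.94.

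The S and G2/M phase list had a median of 0.74 (random -0.25 to 0.54), with Cdk1 at 1.41, Ccnb1 at 1.40, Tpx2 at 1.40 and Cenpf at 1.28. This direction rested on the cluster of 127 cells. The list median was -0.97 with cells under 1000 detected genes or over 5% mitochondrial UMIs left out and -0.88 with predicted doublets kept, settings in which 0 of that cluster's cells kept the myofibroblast-like name. The median of all 15421 tested genes was 0.17. A minimum of 100 UMIs moved the ligands to 2.87, the adrenergic receptors to -2.64 and the growth factor list to 1.58, and a minimum of 1 UMI moved the ligands to 1.41 and the acetylcholine receptors to -0.25. The stricter cell filter moved the neuropeptide receptors to -0.99 (random -1.17 to 0.94) and put the adrenergic receptors at -1.10 (random -1.13 to 1.11). With predicted doublets kept, the neuropeptide receptors were at -1.18 (random -1.46 to 0.87). With a minimum of 1 UMI the planar cell polarity list was at 0.55, inside its random range (-0.13 to 0.62).

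**Figure D2:**
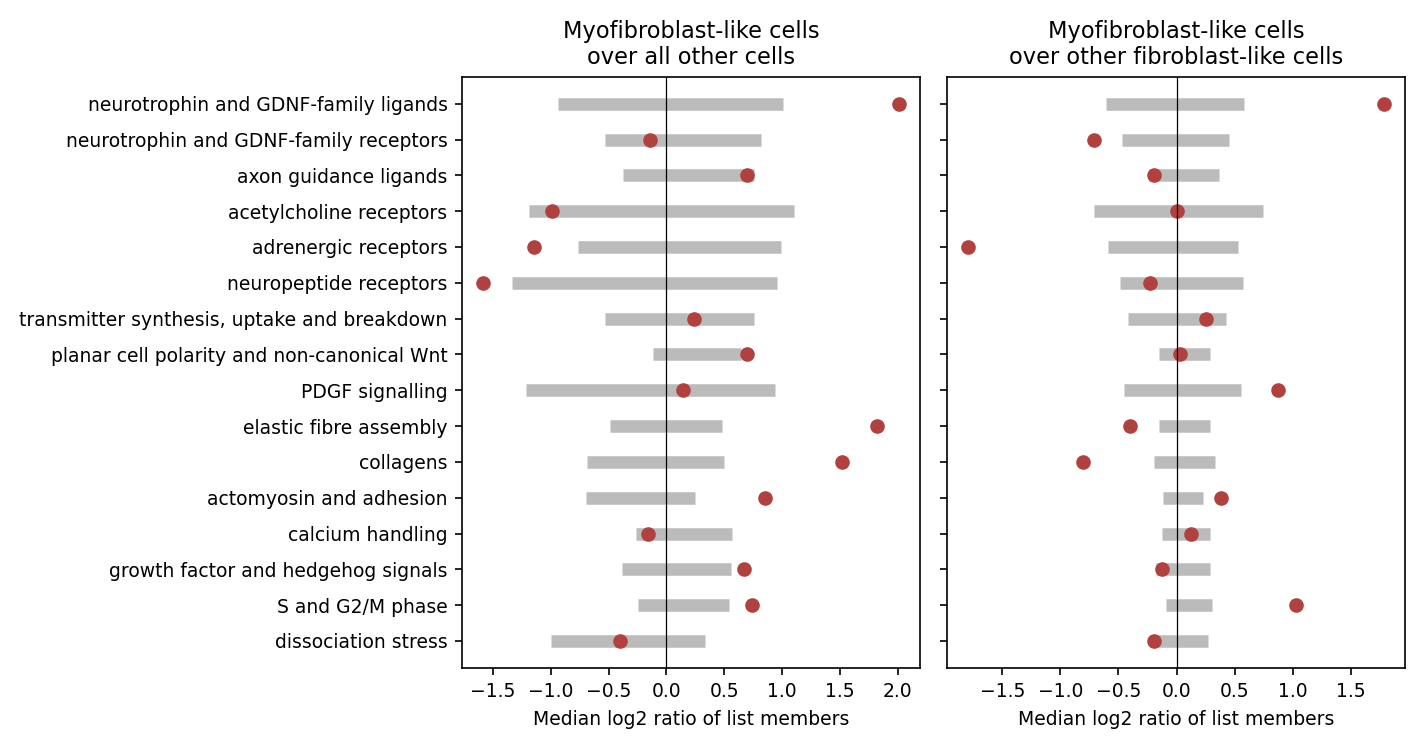
Points give the median log2 ratio of each fixed list, for myofibroblast-like cells over all other cells and over other fibroblast-like cells, and grey bars the middle 95% of random lists matched on level. The ligand list stood at 2.01 and 1.78, and the adrenergic receptor list at -1.14 and -1.79; the S and G2/M list, at 0.74 and 1.02, turned to -0.97 and -0.49 with the stricter cell filter.

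The second comparison set the myofibroblast-like cells against the other fibroblast-like classes, lipofibroblast or matrix and adventitial. Nrtn was again higher in myofibroblast-like cells, at 97.1 against 11.2 CPM, and so were Bdnf (40.2 against 5.43) and Wnt11 (153 against 9.84). Adra1b, an alpha-1 adrenergic receptor gene, was lower, at 0.753 against 80.4 CPM. The collagen and elastic fibre lists, higher against all other cells, were lower against other fibroblast-like cells.

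The ligand list had a median log2 ratio of 1.78 (random -0.61 to 0.58), with Nrtn at 3.01, Gdnf at 2.91, Bdnf at 2.68, Ntf3 at 0.89 and Ntf5 at -0.43. Gdnf and Ntf5 had under 100 UMIs. Smooth muscle-like cells, where Bdnf and Ntf3 were highest, are not in this comparison. Nrtn was detected in 5.91% (4.54% to 7.54%) of other fibroblast-like cells, and Bdnf in 12.98% (10.5% to 15.8%) of myofibroblast-like, 2.07% (1.29% to 3.15%) of other fibroblast-like and 0.117% (0.0381% to 0.273%) of myeloid-like cells. Median detected genes were 2807 in myofibroblast-like, 2359 in lipofibroblast or matrix-like, 2727 in adventitial fibroblast-like and 1961 in myeloid-like cells. The ligand receptors had a median of -0.71 (random -0.47 to 0.45), with Gfra2 at -0.71 and Sort1 at -1.31. Adrenergic receptors had a median of -1.79 (random -0.59 to 0.53), or -1.39 with members at 0 set to the floor. Adra1b stood at -5.54, Adrb3 at -3.34, Adrb1 at -1.20 and Adra2a at 1.66. Adra1b was detected in 34.7% (31.8% to 37.7%) of other fibroblast-like cells, 0.458% (0.0946% to 1.33%) of myofibroblast-like cells and 0.305% (0.162% to 0.521%) of myeloid-like cells. The share in myofibroblast-like cells was therefore within the background. Acetylcholine receptors (0.00, random -0.71 to 0.74) and neuropeptide receptors (-0.23, random -0.48 to 0.58) were inside their random ranges, and with members at 0 set to the floor their medians were 0.22 and 0.39.

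Collagens had a median of -0.80 (random -0.20 to 0.33), and Col13a1, a marker of matrix fibroblasts, stood at -5.11 while Col12a1 stood at 2.56. The elastic fibre list was at -0.40 (random -0.15 to 0.28), although Loxl2 (2.72) and Ltbp2 (2.63) were higher in myofibroblast-like cells. Actomyosin and adhesion genes were at 0.38 (random -0.12 to 0.23), with Tpm1 at 1.86 and Cald1 at 1.77. The PDGF list was at 0.87 (random -0.45 to 0.56), with Pdgfra at 2.19 and Pdgfrb at 1.20. Pdgfra was detected in 70.1% (66.4% to 73.6%) of myofibroblast-like, 30.6% (27.8% to 33.6%) of other fibroblast-like and 1.22% (0.912% to 1.60%) of myeloid-like cells. Axon guidance ligands (-0.19, random -0.24 to 0.37) were inside their random range, with Sema3c at 2.95, Ntn1 at 1.53 and Slit3 at -4.92. Planar cell polarity and non-canonical Wnt genes (0.03, random -0.15 to 0.29) were inside theirs, with Wnt11 at 3.82 and Wnt5a at 2.24. So were the transmitter (0.26, random -0.42 to 0.42), calcium handling (0.12, random -0.12 to 0.29), growth factor (-0.13, random -0.18 to 0.28) and stress lists (-0.19, random -0.23 to 0.27). The S and G2/M list was at 1.02 (random -0.09 to 0.30), but at -0.49 with the stricter cell filter and -0.59 with predicted doublets kept. The median of all tested genes was 0.07. With a minimum of 100 UMIs the ligands were at 2.68, the acetylcholine receptors at -0.60 and the adrenergic receptors at -1.20, and with a minimum of 1 UMI the ligands were at 0.89 and the adrenergic receptors at -1.20. The stricter cell filter moved the adrenergic receptors to -1.21 and put the stress list at -0.40, outside its random range (-0.35 to 0.25). With predicted doublets kept, the axon guidance ligands were at -0.26, outside theirs (-0.24 to 0.36).

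Most of the named receptor genes for transmitters and neurotrophic ligands had their highest level in a class other than the myofibroblast-like cells, Adra2a being an exception at 3.77 CPM. The share over all tested genes was not counted, so this cannot be called particular to receptor genes. Adra1b was highest in lipofibroblast or matrix-like cells (103 CPM), as was Adrb3 (14.1). Adrb1 was highest in endothelial-like cells (97.8), as was Calcrl (801). Chrm2, encoding a muscarinic acetylcholine receptor, was highest in mesothelial-like cells, at 145 CPM and in 37.8% (23.8% to 53.5%) of 45 cells against 0% (0% to 0.0865%) of myeloid-like cells, with median detected genes of 2926 and 1961. Ntrk3, the receptor gene for neurotrophin 3, stood at 209.7 CPM in smooth muscle-like cells, which also had the highest levels of Ntf3 (95.6) and Bdnf (112). Sstr2 was highest in pericyte-like cells, in 36.5% (28.7% to 44.8%) of 148 cells against 0.281% of myeloid-like cells, with median detected genes of 2247 and 1961. Npy2r was highest in alveolar type 2-like cells (61.8) and Rspo1 in mesothelial-like cells (869). Gfra2 was at 135 in adventitial fibroblast-like, 126 in lipofibroblast or matrix-like and 78.1 in myofibroblast-like cells.

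**Figure D3:**
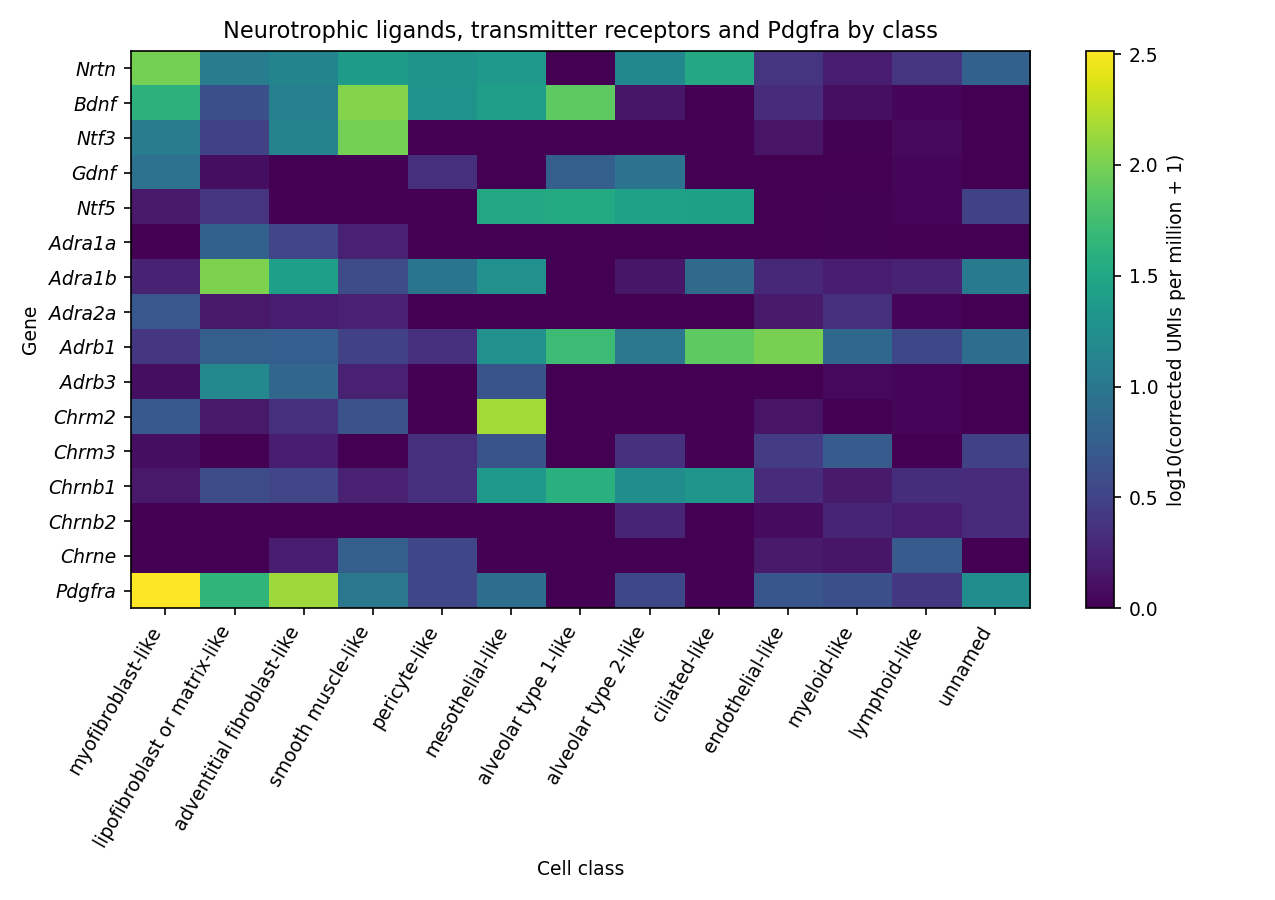
Colour gives the log10 of CPM plus 1 for the ligand genes, adrenergic and acetylcholine receptor genes named in the text and Pdgfra in each class. Nrtn and Pdgfra were brightest in myofibroblast-like cells, at 97.1 and 327 CPM, and Adra1b in lipofibroblast or matrix-like cells, at 103.

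The bulk library showed what the sorted PDGFRA+ cells expressed. Median levels were high for matrix and contractile genes and for fibroblast markers, and lower for markers of immune, endothelial and neural cells. Pdgfra stood at 184 (95% interval 182 to 186) CPM, Nrtn at 62.9 (95% interval 61.7 to 64.1), Wnt5a at 199.8 (95% interval 198 to 202) and Wnt11 at 251 (95% interval 249 to 253). Haemoglobin genes were an exception: 7 of them took 1.06% of the reads (95% interval 1.06% to 1.06%).

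Median ranks among 16905 genes, where 100 is the highest, were 99.8 for collagens, 99.0 for elastic fibre genes, 98.5 for stress genes and 98.2 for actomyosin genes. Growth factor and hedgehog signals ranked at 77.7, S and G2/M genes at 76.6, planar cell polarity and non-canonical Wnt genes at 75.1 and calcium handling genes at 67.1. Axon guidance ligands ranked at 59.1, PDGF genes at 55.3, the ligand receptors at 40.8 and the ligands at 40.1. Transmitter genes ranked at 29.6, adrenergic receptors at 28.6, neuropeptide receptors at 20.9 and acetylcholine receptors at 18.5. The bulk table listed genes with reads only, so members not listed have no rank. In these lists 13 of 16, 8 of 9, 13 of 17 and 13 of 21 members were listed. Of the 8 adrenergic receptors listed, 6 were at 1 CPM or more and Adra1b alone was at 10 or more (18.8 (95% interval 18.1 to 19.4)). Gfra2 stood at 173 (95% interval 171 to 175) and Ret at 0.558 (95% interval 0.452 to 0.682). Leaving out genes under 1 CPM changed which members were ranked and moved the adrenergic receptors to 9.11 and the acetylcholine receptors to 6.81.

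Among cell type markers, median TPM was 632 for adventitial fibroblast, 344 for myofibroblast, 222 for smooth muscle and 87.8 for lipofibroblast or matrix fibroblast markers. It was 21.0 for pericyte, 6.02 for mesothelial and 6.25 for cartilage markers. Epithelial medians were 10.4 for alveolar type 1, 5.96 for alveolar type 2, 10.6 for secretory airway, 0.990 for ciliated and 0.185 for neuroendocrine markers. Single epithelial genes stood higher, with Sftpc at 211 and Scgb1a1 at 242 TPM. Endothelial medians were 7.95 for general endothelial, 1.52 for general capillary, 9.10 for aerocyte, 6.33 for arterial, 10.5 for venous and 0.440 for lymphatic markers. Single endothelial markers reached 171 (general), 126 (aerocyte) and 111 (arterial) TPM. General immune markers had a median of 15.1 and a median rank of 37.5 with CPM or 60.9 with TPM, with Ptprc at 1.99. Macrophage medians were 1.15 (alveolar) and 6.88 (interstitial), with a highest alveolar macrophage marker of 121, and those of monocytes, neutrophils and dendritic cells 2.73, 5.61 and 0.170. Median TPM was 1.52 for B cell, 0.400 for T cell, 0.340 for NK cell, 0.420 for innate lymphoid and 0.410 for mast cell or basophil markers. Neuron and glia markers were at 0.505 and 0.240, and megakaryocyte or platelet markers at 3.00. Erythroid markers were at 6539, with Hba-a1 at 16600.0 and Alas2 at 116 TPM.

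The next comparison asked which single-cell class the bulk profile ranked most like. Adventitial fibroblast-like and myofibroblast-like cells came closest, with Spearman correlations across 15058 genes of 0.843 and 0.840. With TPM in place of CPM the order of these classes turned, to 0.836 and 0.841. Lipofibroblast or matrix-like cells followed at 0.807, smooth muscle-like cells at 0.788 and pericyte-like cells at 0.761. The whole library was at 0.716, endothelial-like cells at 0.715, mesothelial-like cells at 0.703 and the unnamed cluster at 0.690. Alveolar type 1-like cells were at 0.624, alveolar type 2-like at 0.614, myeloid-like at 0.608, lymphoid-like at 0.583 and ciliated-like at 0.511. Genes are not independent replicates, so no p is given, and the small classes hold fewer UMIs.

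The last comparison set the sorted bulk library over the summed single-cell library, with sort, assay and genotype differing together. Collagen, elastic fibre and planar cell polarity genes were higher in the bulk. Of 15 collagens all were at a log2 ratio of 1 or more, as were 19 of 20 elastic fibre genes. Bulk CPM is not corrected for gene length, and with TPM, which is, the counts were 13 of 15 and 18 of 20. The lowest 2 of the named genes were S100a8 and S100a9, which encode calprotectin, at log2 ratios of -10.64 and -9.82.

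List medians were 4.54 for collagens (random -1.86 to 1.31), 3.75 for elastic fibres (random -1.22 to 1.46), 2.09 for planar cell polarity and non-canonical Wnt (random -0.53 to 0.80) and 1.94 for axon guidance ligands (random -0.66 to 1.13). The ligands were at 1.72 (random -1.36 to 1.31), their receptors at 1.71 (random -1.26 to 1.24) and the growth factor list at 1.03 (random -0.63 to 1.02). Inside their random ranges were PDGF (1.40, random -1.61 to 1.53), actomyosin (1.10, random -0.81 to 1.60) and stress genes (0.81, random -1.38 to 1.90). The transmitter (0.49, random -0.59 to 0.51), acetylcholine receptor (0.19, random -0.75 to 0.42), S and G2/M (0.13, random -0.40 to 1.05) and neuropeptide receptor lists (-1.07, random -1.10 to 0.95) were inside theirs too. Adrenergic receptors were at 0.43 (random -1.34 to 1.15), or -0.18 with TPM, and calcium handling genes at 0.04 (random -0.68 to 0.95), or -1.44 with TPM, outside the random range (-0.92 to 0.49). The neuropeptide receptors with TPM (-1.31, random -1.21 to 0.67), the PDGF list with a pseudocount of 0.1 (1.70, random -1.79 to 1.68) and the transmitter genes with one of 5 (0.25, random -0.23 to 0.24) were outside too. The median of all genes compared was 0.08, and -0.15 with TPM. Summed over the fibroblast-like and myofibroblast-like cells only, the growth factor list was at -0.043, the adrenergic receptors at -0.72, the collagens at 2.39 and the elastic fibre list at 1.81. Beside these, the stress list was at 1.43 and the acetylcholine receptors at 0.28, both outside their random ranges (-0.83 to 1.23 and -0.45 to 0.21). The ligands were then at 0.45, inside their random range (-0.98 to 1.03), as they were with a pseudocount of 5 (0.70, random -0.68 to 0.71). The growth factor list was inside its random range in 4 of the 6 alternatives. With TPM the planar cell polarity list was at 0.80, the collagens at 2.37, the actomyosin list at 0.11 and the growth factor list at 0.13.

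The 10 highest genes were Hba-a1 (10.48), Hbb-bs (9.61), Atp6v0c (6.31), Pcdhgc3 (6.24), Col2a1 (6.20), Col5a1 (5.48), Lrrc15 (5.46), Sept5 (5.45), Col6a2 (5.42) and Ltbp2 (5.41). Hba-a1 (mm10 chromosome 11, 32283511 to 32284465) stood at 4125 CPM in the bulk and 1.88 CPM in the library. Pcdhgc3 and Sept5 share exonic bases with other genes on the same strand (38.5% and 83.7% of their bases). The 10 lowest were S100a8, S100a9, BC100530 (-9.54), Gm5483 (-8.99), Retnlg (-8.82), Ccl5 (-8.45), Stfa2l1 (-8.25), Camp (-8.09), Tyrobp (-8.07) and Stfa2 (-7.87). S100a8 (mm10 chromosome 3, 90668978 to 90670035) stood at 3.88 CPM in the bulk and 7785 CPM in the library.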

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

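The alternatives were fixed before the data were examined, except the list medians with genes at 0 set to a floor of 3 corrected UMIs, chosen after seeing the data. The limits for calling a value moved were also set afterwards: 1.5-fold for list medians, the 95% interval for shares, 0.02 for rank correlations and 10 points for bulk ranks. With no replicates, these limits are not a spread between samples. No paired analysis was possible because each group has 1 sample and no numbers shared between groups link them. Within these limits stayed 71 of 88 class shares, 168 of 176 list medians over all other cells, 167 of 176 over other fibroblast-like cells, 62 of 97 bulk ranks, 97 of 114 rank correlations and 71 of 96 bulk over library medians. These totals, and the counts of random-range calls below, include settings that changed nothing. At resolution 0.5 and 2 every list median over all other cells equalled its main value. The UMI minima left several lists, such as S and G2/M, with the same members. Not run were thinning (the values were taken as already corrected), and TMM scaling and leaving out replicates (1 column). Leaving out mitochondrial genes was not run for bulk ranks and correlations (the bulk table lists none). No value could be had for the ciliated-like class with the stricter cell filter, for the unnamed class with every deposited cell or list genes kept (a secretory airway class of 1.77% or 2.27% appeared instead), or for NK cell markers without low genes. Except where a reason is given, the cause was not tested.

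With every deposited cell, the shares were ciliated 0.365%, endothelial 11.2% and myeloid 39.6%. With cells under 1000 detected genes or over 5% mitochondrial UMIs left out, they were adventitial fibroblast 3.11%, alveolar type 2 4.59%, endothelial 7.99%, lipofibroblast or matrix 5.32%, myeloid 43.3%, myofibroblast 4.92%, pericyte 0.925% and unnamed 4.74%. Under that filter the neuropeptide receptors over all other cells were at -0.99, the adrenergic receptors over other fibroblast-like cells at -1.21, and the correlations at 0.573 (alveolar type 1), 0.738 (pericyte) and 0.728 (unnamed). The S and G2/M list reversed there, to -0.97 over all other and -0.49 over other fibroblast-like cells, and also with predicted doublets kept, to -0.88 and -0.59, because 0 of the 93 and 127 remaining cells of the cycling cluster were then named myofibroblast-like: their best marker score was for smooth muscle and they were left unnamed. In the other clustering alternatives all 127 kept the name. Keeping doublets gave shares of 39.5% (myeloid), 5.10% (myofibroblast) and 6.22% (unnamed) and a correlation of 0.745 (unnamed). The adventitial share was 2.40% at resolution 0.5, and the unnamed share 2.54% at resolution 2 and 1.77% with 15 principal components.

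A minimum of 100 UMIs, which leaves fewer genes, gave over all other cells 2.87 for the ligands, -2.64 for adrenergic receptors and 1.58 for growth factor and hedgehog signals, and over other fibroblast-like cells 2.68 for the ligands, -0.60 for acetylcholine receptors and -1.20 for adrenergic receptors. A minimum of 1 UMI, which adds genes, gave 1.41 (ligands) and -0.25 (acetylcholine receptors) over all other cells and 0.89 (ligands) and -1.20 (adrenergic receptors) over other fibroblast-like cells. The floor moved the neuropeptide receptors over other fibroblast-like cells from -0.23 to 0.39, and put the ligand receptors over all other cells at 0.15 in place of -0.14.

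Of the list medians outside the random range in the main settings, 4 of 99 over all other cells, 0 of 88 over other fibroblast-like cells and 6 of 42 for bulk over library fell inside it under an alternative. Over all other cells these were adrenergic and neuropeptide receptors with the stricter cell filter, neuropeptide receptors with doublets kept and planar cell polarity with a minimum of 1 UMI. For bulk over library they were the ligands with a pseudocount of 5, the growth factor list without genes under 1 CPM, with TPM and with a pseudocount of 0.1, and both when summed over the fibroblast-like and myofibroblast-like cells only. Of those inside it, 0 of 77, 2 of 88 and 6 of 54 fell outside. Over other fibroblast-like cells these were stress genes with the stricter cell filter and axon guidance ligands with doublets kept. For bulk over library they were neuropeptide receptors and calcium handling with TPM, PDGF with a pseudocount of 0.1, transmitter genes with one of 5, and acetylcholine receptors and stress genes when summed over the fibroblast-like and myofibroblast-like cells only. The counts take no account of direction. With the stricter cell filter and with doublets kept, the S and G2/M list counted as staying outside but lay below the random range, where the main median lay above it. That held over all other and over other fibroblast-like cells.

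Leaving out genes under 1 CPM, which removes low members and shifts the scale of ranks, gave bulk ranks of 24.3 for ligands, 6.81 for acetylcholine receptors, 9.11 for adrenergic receptors and 40.4 for PDGF genes. Marker ranks were then mesothelial 19.6, alveolar type 1 29.4, alveolar type 2 22.2, secretory airway 18.3, ciliated 2.38, neuroendocrine 78.8, general endothelial 22.0, general capillary 8.98, aerocyte 37.2, arterial 26.3, venous 36.0 and lymphatic 6.19. They were alveolar macrophage 6.97, interstitial macrophage 12.99, monocyte 8.53, neutrophil 10.7, B cell 4.58, T cell 2.03, innate lymphoid 5.14, general immune 16.6, platelet 15.1, neuron 0.390, glia 36.4 and cartilage 28.7. The correlations were adventitial fibroblast 0.760, myofibroblast 0.755, lipofibroblast or matrix 0.703, smooth muscle 0.689, pericyte 0.660, mesothelial 0.608, endothelial 0.595, unnamed 0.593, alveolar type 1 0.529, alveolar type 2 0.505, myeloid 0.488, lymphoid 0.457 and ciliated 0.449. The bulk over library medians were 0.90 for acetylcholine and -0.40 for neuropeptide receptors.

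With TPM, bulk ranks were 63.0 for planar cell polarity, 56.5 for calcium handling, 67.5 for growth factor genes, 52.9 for secretory airway, 46.6 for interstitial macrophage, 43.7 for neutrophil and 60.9 for general immune markers. Over the library, TPM gave axon guidance 1.24, adrenergic receptors -0.18, planar cell polarity 0.80, elastic fibre 3.00, collagens 2.37, actomyosin 0.11, calcium handling -1.44 and growth factor 0.13. A pseudocount of 0.1 put the ligands at 2.60, and one of 5 put the ligands at 0.70, their receptors at 1.07, neuropeptide receptors at -0.43 and PDGF genes at 0.81. Summed over the fibroblast-like and myofibroblast-like cells only, the growth factor list reversed to -0.043. The others were ligands 0.45, axon guidance 0.81, adrenergic receptors -0.72, neuropeptide receptors 0.012, planar cell polarity 0.74, elastic fibre 1.81, collagens 2.39, actomyosin 0.46 and stress 1.43.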

Other observations

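The tests chosen only after the result was seen were the globin level as a percent of the bulk level, the comparison with lipofibroblast-like cells alone, and the 3 on whether overlap, the sort or transcript length accounts for all 10 highest genes. The genes of the next paragraph, and Igf2 below, were also chosen after their values were seen.

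Pdgfa, the ligand gene for PDGFRA, stood at 1028 CPM in alveolar type 1-like cells, and was detected in 97.2% (85.5% to 99.9%) of the 36 cells against 1.69% (1.32% to 2.12%) of myeloid-like cells, with median detected genes of 2340.5 and 1961. In smooth muscle-like cells Npy1r, a receptor gene for the sympathetic co-transmitter neuropeptide Y, stood at 53.6 CPM and in 24.8% (19.5% to 30.7%) of 246 cells, against 0.0469% (0.00568% to 0.169%) of myeloid-like cells, with median detected genes of 2396.5 and 1961. Pdgfrb was highest in pericyte-like cells, at 1259 CPM. Igf2 was at 748 CPM in the bulk, while the single-cell table held 33 corrected UMIs of it, and 62.8% of its exonic bases lie in another gene's exons on the same strand.

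Haemoglobin genes took 1.06% of the bulk reads (10628 CPM over 7 genes), against 6.78 CPM over 4 listed genes in the fibroblast-like and myofibroblast-like cells of the single-cell library. The latter is 0.0638% of the former, a test chosen after the result was seen. Of genes in both, Hba-a1 stood at 4125 CPM in the bulk and 1.92 in these classes, and Hbb-bs at 3140 and 3.34. This argues against transcription by the PDGFRA+ cells themselves only as far as these classes stand for them. They are wild-type cells in another assay, and Pdgfra was not detected in all of them. The globin level of these classes was 1.28 times that of myeloid-like and lymphoid-like cells, between the bounds of 2 and 1 set beforehand, which decides nothing. RNA of red cells carried into the sort, which selected PDGFRA+ cells, stays open, since 3 of 9 further erythroid genes (Slc4a1 6.47, Trim10 1.90 and Tspo2 1.63 TPM) reached 1 TPM, between the bounds of at least 5 and at most 2 set beforehand. The genotype differs between the samples and was not tested as a biological explanation.

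Among the 10 genes highest in the bulk over the single-cell library, reads lost in the single-cell counting where gene models overlap on the same strand may account for 2 (Pcdhgc3 and Sept5), where random sets had a median of 0 and an upper bound of 1. As the cause for all 10 it was argued against by the 8 genes without such overlap. Enrichment of fibroblast-type genes by the sort may contribute, with a median log2 ratio of 2.78 for fibroblast-like and myofibroblast-like over other cells, but 4 genes (Hba-a1, Hbb-bs, Atp6v0c and Sept5) were at 0.38 or less, which argues against it for all 10. Longer transcripts were argued against as the cause for all 10 by 3 genes below the random median of 3862 bases (Hbb-bs 768, Hba-a1 812 and Atp6v0c 3384), and stay open for the others, with a median of 5404.5 over the 10 and a random upper bound of 6823. No biological explanation other than the sort was tested, and assay and genotype differ with it.

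The S and G2/M list was higher in myofibroblast-like than in other fibroblast-like cells, and 1 cluster of 127 cells had the higher level (10139 CPM, against 939.8 in the other cluster and 12228 in 1 lipofibroblast-like cluster). Few cycling cells in the adventitial comparator were argued against as the cause, since the median log2 ratio against lipofibroblast-like cells alone was 0.77. Cells of other fibroblast types within the cycling myofibroblast-like cluster stay open. The share of cells with more other-fibroblast than myofibroblast marker value was 0% in both myofibroblast-like clusters. It was 99.7% in lipofibroblast or matrix-like and 94.7% in adventitial fibroblast-like cells. The same markers had named the clusters and were not kept out of the variable genes, so this outcome was partly fixed in advance. More detected genes per cell in the myofibroblast-like class may account for part: the median over 4 bins of detected genes was 0.87, but the bins ran from 1.46 down to 0.43. Leaving the cluster out gave -0.50, a test whose prediction, though written beforehand, was badly built, since removing cycling cells lowers the list whatever their type. A smooth muscle identity of the cluster, its best score under 2 alternative settings, stays open: its smooth muscle and myofibroblast marker means per cell (3.99 and 2.56) do not set it apart from the other cluster (7.40 and 4.77), and no biological explanation was tested.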
